A study of Homo sapiens with 8 samples.

How the data were processed

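RNA was measured by sequencing in 8 libraries of HEK293T, a human embryonic kidney line that carries the SV40 large T antigen and is widely used for transient transfection. Per the labels, 4 libraries came from normal cells and 4 from cells given a tagged open reading frame of human KCNQ3, with harvest 48 hours after transfection. The labels attach the same transfection text to every sample, so whether the control cells received transfection reagent or an empty plasmid is not given in the sources used here. The series calls the 4 libraries of a group biological replicates. Nothing states that they came from cultures started separately, so p-values measure only the spread between these samples, which may be technical.

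Per the submitters' processing notes, the tools were cutadapt 2.8, FastQC 0.11.5, HISAT2 2.1.0, SAMtools 1.9 and StringTie 2.1.0, and the genome build was GRCh38.p13. The role of each tool, the annotation release, the read length and whether counting used strand are not given in the sources used here. The authors deposited estimated counts per transcript and, in a second table, TPM (length-scaled levels that sum to 1000000 per library) per transcript, each for 227751 Ensembl transcript identifiers. The deposited estimated counts were whole numbers. Among transcripts with at least 1000 counts, 74.7% to 75.2% per library lay within 2% of the library's median ratio of count to TPM times length. No count was 0 where TPM was above 0. The counts therefore follow estimated coverage rather than a tally of reads, and reads shared by isoforms, overlapping genes or near-identical copies were divided by the authors' estimate.

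Transcripts were joined to genes by identifier through GENCODE release 29 (GRCh38), whose coordinates are the ones printed. Of the identifiers, 205804 matched and 21947 did not. The unmatched ones, of which 6339 had a count, entered only the transcript test. Matched transcripts held 98.7% to 98.9% of the counts in each library. Counts were summed per gene without further rounding, as they were already whole. No row lacked a transcript name.

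Total counts ran from 24020097 to 30734915 per library. Replicates were compared before use. The 12 pairs within a group differed by 9.72 to 18.6 chi-square units per degree of freedom over genes with at least 20 counts in the pair, so no library was a second copy of another. Ratios of summed counts are scaled by the summed TMM-scaled library sizes of the groups. Their intervals are exact 95% intervals and, like the floor of 3 counts over a group used where a group had none, cover counting error only.

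The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust estimation) on TMM-scaled counts of features kept by filterByExpr (minimum count 10, minimum total 15), with Benjamini-Hochberg adjustment and a threshold of 0.05. It was run on genes and on transcripts, 4 libraries against 4, without covariates. Levels are CPM (counts per 1000000 counts of a library) with TMM scaling, as mean ± SD over 4 libraries, and log2 fold changes are overexpression over control with the standard error implied by the test. The level of KCNQ3 also had an exact two-sided permutation test of log2(CPM + 1) over the 70 assignments of the labels. Transcript usage was tested with edgeR's diffSpliceDGE (Simes p per gene). The 25 gene lists, fixed before the data were examined, were tested with limma 3.58.1's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, again with the correlation estimated for each list, and with fry (directional and mixed). The counts of members past the threshold were taken over all genes and with p adjusted over the list alone, which does not adjust for the number of lists.

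The genes named were set by a rule, also fixed before the data were examined. It took KCNQ3. From the genes past the threshold with at least 1 CPM in a group, a proper symbol and no overlap between groups, it took the 12 largest rises and the 12 largest falls. From each list it took up to 4 members past the threshold, or the 2 most abundant where none passed. Transcripts and usage had like rules. Most list members named as passing only with p adjusted over the list alone lie outside the rule and were picked with their values known. Not all of the abundant members that the rule took are printed. Other genes named outside the rule are said to be so where they appear.

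The tests were tested on simulated data drawn from the real means, spreads and library sizes. Over 19280 genes with 200 changed, the gene test recovered 36% of the genes changed by 1.25 times, 50% at 1.5 times, 78% at 2 times and 96% at 4 times, and 11 of its 141 calls were false. Over 47129 transcripts, the test recovered 0% of those changed by 2 times, 6% at 4 times, 34% at 16 times and 44% at 64 times, with 0 false calls among 42. The list test found the 1 shifted list and called 0 of the others. Genes were drawn independently in that simulation, so it could not show false calls that arise where members of a list move together. The usage test failed: over 9395 genes, 125 of its 167 calls were false with 200 genes changed, and it called 97 genes when no gene was changed. It pools 1 spread per gene over transcripts whose spreads differ. It was kept because it had been fixed in advance, and its calls are given without being read as changes. A test added after seeing the data, in which each transcript keeps its own spread, made 1 false call among 28 with 200 genes changed and 0 when none was.

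Alternatives covered scaling (DESeq2's size factors, none, or factors computed without KCNQ3 and the mitochondrial genes), filters, DESeq2 1.42.0, limma-voom, TPM on a log2(TPM + 1) or log2(TPM + 0.1) scale with limma, a replicate block, a stricter threshold, a minimum change, and each library left out. Offsets fitted on GC content and length, the KCNQ list without KCNQ3, and the usage test with each transcript's own spread were added after seeing the data. For camera the offsets were subtracted from log2 CPM that had already been scaled by them, so its results with offsets carry more than 1 correction.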

Results

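The series compared HEK293T cells overexpressing KCNQ3, a subunit of the voltage-gated potassium channels that carry the neuronal M-current, with normal HEK293T cells. Total RNA was extracted, and how messenger RNA was selected is not given in the sources used here. Each group had 4 libraries. Total estimated counts were 30734915, 26484905, 24020097 and 25764911 in control replicates 1 to 4 and 26639645, 24738542, 27542588 and 24806193 in overexpression replicates 1 to 4. Mitochondrially encoded genes took 3.99% to 5.59% of the counts in controls and 4.82% to 5.84% in overexpression libraries. Of 34290 genes with a count, 19280 were tested.

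KCNQ3 (ENSG00000184156, chromosome 8, 132120858 to 132481019, GRCh38) was almost absent from control cells and abundant after overexpression, which checks the labels. Its counts were 4, 5, 0 and 2 in control replicates 1 to 4 and 15283, 15874, 19709 and 18603 in overexpression replicates 1 to 4. The level went from 0.0996 ± 0.080 to 684 ± 88.0 CPM (mean ± SD, n = 4 per group), and KCNQ3 ranked 142 among all genes in the overexpression libraries. The ratio of the summed counts, each divided by its group's summed TMM-scaled library size, was 6600 (95% interval 3688 to 13222, counting error only). The log2 fold change was 12.63 (SE 0.25), with an adjusted p of 6.46e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The exact two-sided permutation test gave p = 0.0286, the smallest that 70 assignments allow. Of 8 annotated KCNQ3 transcripts, 2 had counts. ENST00000388996 (11510 bases) held 78.7% ± 7.8 of the gene's counts in the overexpression libraries and ENST00000521134 (2577 bases) held the rest. The construct carries an open reading frame, so the division between transcripts that differ outside it was an estimate.

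**Figure D1:**
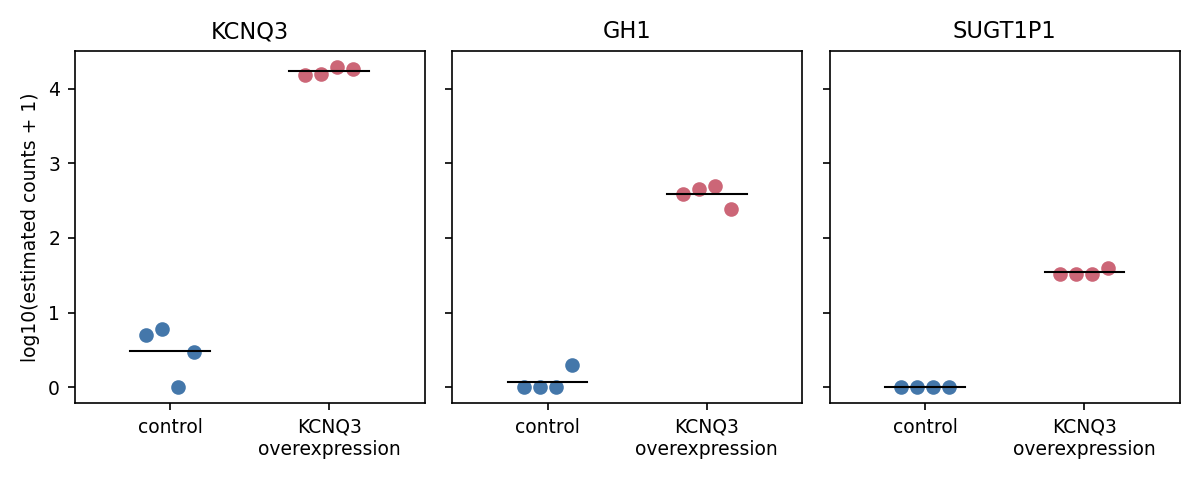
Estimated counts of KCNQ3, GH1 and SUGT1P1 in each library, as log10(count + 1), for 4 control (blue) and 4 KCNQ3 overexpression (red) libraries, with black bars at the group means. KCNQ3 reached 15283 to 19709 counts in the overexpression libraries against at most 5 in controls, and GH1 and SUGT1P1 had counts almost exclusively in the overexpression libraries.

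Beyond KCNQ3, 2 genes were close to absent in controls and present in every overexpression library. GH1 (ENSG00000259384, chromosome 17, 63917200 to 63918838), which encodes pituitary growth hormone, had 0, 0, 0 and 1 counts in controls and 387, 456, 494 and 244 in overexpression libraries, a ratio of 1652 with the same scaling (95% interval 296 to 65300, counting error only; adjusted p = 5.06e-04). SUGT1P1, a pseudogene of the co-chaperone gene SUGT1, had no counts in controls and 32, 32, 32 and 39 in overexpression libraries, at least 47.0-fold higher with that scaling against a floor of 3 counts over the control group (adjusted p = 6.21e-04). Identical stretches reached 154 bases between GH1 and GH2 and 69 bases between SUGT1P1 and SUGT1. SUGT1 had 1252 to 1621 counts in controls and 1215 to 1419 in overexpression libraries, so the counts given to SUGT1P1 depend on the authors' division of reads. A constant share of SUGT1 reads would have put counts in controls too. Whether the division differed between groups was not tested. GH2, CSH1, CSH2 and CSHL1 together had 15 counts in the overexpression libraries, which leaves few reads to divide with GH1. Other rises were small. GOT1-DT, a noncoding RNA divergent from GOT1, rose from 3.01 ± 0.51 to 7.15 ± 1.01 CPM (2.38 times, log2 SE 0.14). SLC2A1, the glucose transporter GLUT1, rose by 0.44 on the log2 scale (SE 0.07), from 24.8 ± 2.3 to 33.8 ± 1.8 CPM. CTSA, a lysosomal carboxypeptidase, rose by 0.42 (SE 0.05), and CSTB, an inhibitor of lysosomal cysteine proteases, by 0.29 (SE 0.05). NOP16 and WDR77, a nucleolar protein and a subunit of the methylosome, rose by 0.29 each, NDUFAF8, an assembly factor of respiratory complex I, by 0.30, and MFSD3 by 0.32. The antisense transcripts HOXA11-AS and ZNF503-AS2 rose by 0.43 and 0.30, but without known strand their reads cannot be separated from those of the opposite gene.

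CELF3, an RNA-binding splicing regulator of the nervous system, fell from 2.22 ± 0.12 to 0.608 ± 0.12 CPM (log2 −1.86, SE 0.15, adjusted p = 6.21e-04). SYN1, the synaptic vesicle protein synapsin I, fell from 1.87 ± 0.17 to 1.01 ± 0.11 CPM (log2 −0.90, SE 0.13), and RUNDC3A from 2.71 ± 0.32 to 1.48 ± 0.14 CPM (log2 −0.87, SE 0.12). TXNIP, an inhibitor of thioredoxin and of glucose uptake, was the most abundant gene among the 12 largest falls and went from 127 ± 12 to 80.3 ± 5.0 CPM (log2 −0.66, SE 0.07, adjusted p = 0.00580). NR1D1, a transcriptional repressor of the circadian clock, fell by 0.84 on the log2 scale (SE 0.12) and ATF5, a stress-induced transcription factor, by 0.62 (SE 0.10). ASNSP1, a pseudogene of asparagine synthetase that can take reads from ASNS, changed by −0.64. The rest of the 12 largest falls, taken from genes with at least 1 CPM in a group, were VLDLR-AS1 (−1.24, antisense to VLDLR), SH2D3C (−0.90), IQUB (−0.79), CRIP2 (−0.69) and ZNF79 (−0.56). Without known strand, the reads of VLDLR-AS1 cannot be separated from those of VLDLR.

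In all, 58 of 19280 genes passed edgeR's quasi-likelihood test, 21 higher and 37 lower, and 48 of them were protein coding. Of these, 12 changed by more than 2 times, 4 higher (KCNQ3, GH1, SUGT1P1 and GOT1-DT) and 8 lower. In each of the 58 the groups did not overlap. Over all genes tested, 11.6% had groups that did not overlap, against 2.86% by chance. Of the 19280, 3737 had an unadjusted p under 0.05. Members that pass only with p adjusted over a list alone are to be read against that background. Without a scaling factor the split was 9 higher and 26 lower. The excess of lower calls did not hold in every alternative. On both TPM scales 5 were higher and 2 lower, and without overexpression replicate 2 the split was 5 and 3. The number of calls was unstable: it was 19, 20, 15 and 194 without control replicates 1 to 4 and 378, 8, 19 and 15 without overexpression replicates 1 to 4, and DESeq2 called 727 genes, 47 of them among the 58. Of the genes named for passing over all genes, KCNQ3, GH1, SUGT1P1 and CELF3 held their call in each alternative that tested them, and the others lost theirs in part. Of 20 alternatives, GOT1-DT lost its call in 1, ASNS and TXNIP in 3, CTSA and CRIP2 in 4, SH2D3C in 5, NOP16 in 6, and CARS1 and MFSD3 in 8. The call ended more often for RUNDC3A and SLC2A1 (9 of 20), AARS1, CSTB and NR1D1 (10), WDR77, HOXA11-AS, ASNSP1 and ZNF79 (11), and GARS1, ATF5, NDUFAF8 and ZNF503-AS2 (12), and of 18 for SYN1 (9), IQUB (10), VLDLR-AS1 (11) and SNAP25 (12).

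**Figure D2:**
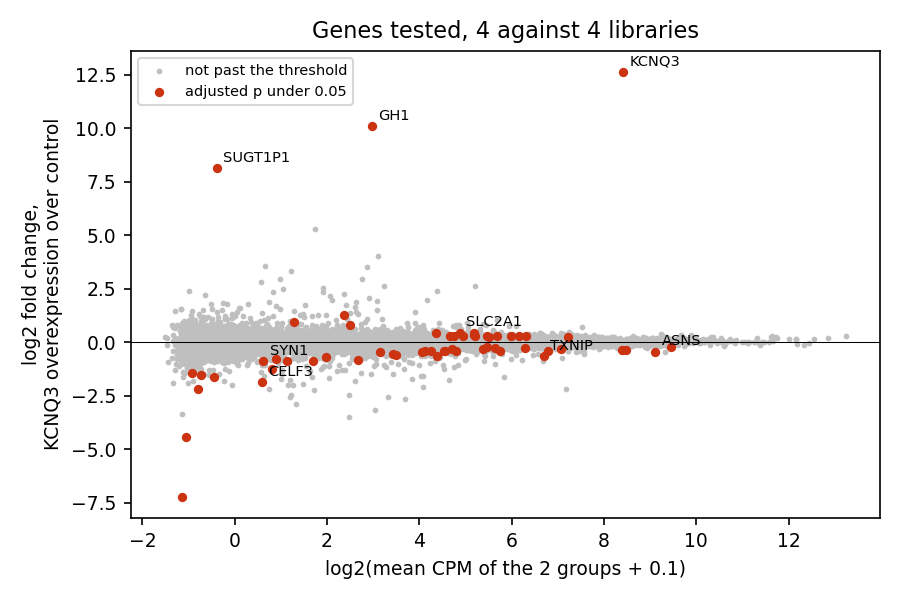
Log2 fold change (KCNQ3 overexpression over control) of 19280 genes against log2 of the mean CPM, with the 58 genes at an adjusted p under 0.05 in red and the others in grey. KCNQ3, GH1 and SUGT1P1 stand above the rest, and 37 of the 58 lie below 0.

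A list held targets of the integrated stress response and of its transcription factor ATF4, with ATF4 itself among them. All 30 tested members had a log2 fold change below 0, with a median of −0.31, and 4 passed over all genes. ASNS, asparagine synthetase, fell from 638 ± 34 to 468 ± 16 CPM (log2 −0.45, SE 0.05, adjusted p = 0.00783). CARS1, AARS1 and GARS1, the cysteinyl-, alanyl- and glycyl-tRNA synthetases, fell by 0.40, 0.36 and 0.35 on the log2 scale (SE 0.05, 0.06 and 0.06). When p was adjusted over the list alone 23 members passed, all lower. Camera gave the list an adjusted p of 1.03e-16 with the preset correlation, and the adjusted p = 0.395 with an estimated correlation (unadjusted p = 0.0467), because its members move together across libraries (estimated correlation 0.504). Fry's directional test, which does not compare the list with other genes, gave an adjusted p of 0.0180. The mean score of the list was lower in every overexpression library than in every control library (exact two-sided permutation p = 0.0286, adjusted over 25 lists 0.238). The gap was small, from 0.0343 in control replicate 4 to 0.0241 in overexpression replicate 1, against SDs of 0.13 and 0.16 within the groups, and the other overexpression libraries were at −0.147, −0.280 and −0.325. Of 25 lists, 3 had scores that did not overlap, the others being the interferon list and the KCNQ list with KCNQ3 itself, where chance gives 2.86%.

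**Figure D3:**
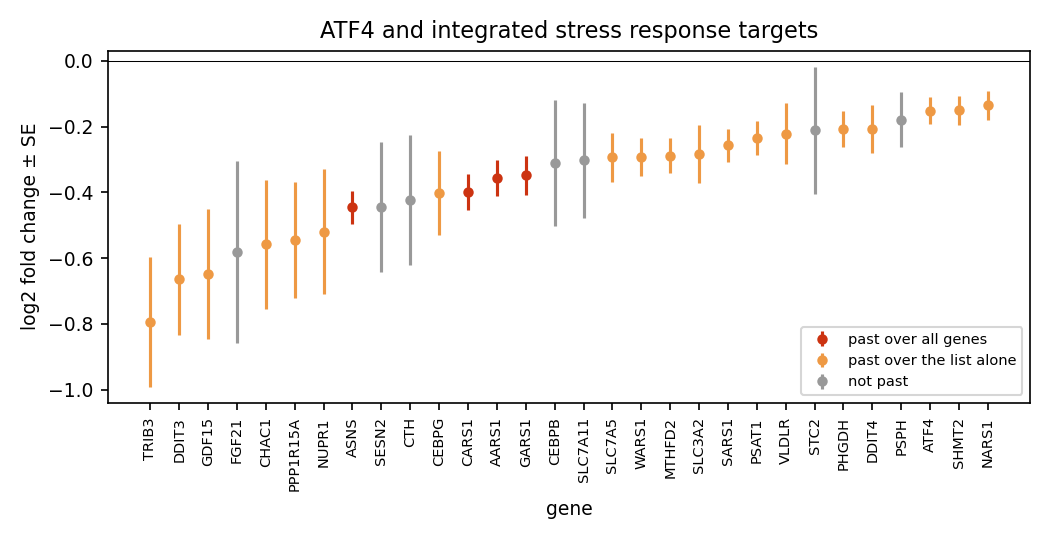
Log2 fold change ± SE of the 30 tested ATF4 and integrated stress response targets, KCNQ3 overexpression over control, 4 libraries each. Red points passed over all genes (4), orange ones with p adjusted over the list alone, and every point lies below 0.

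Camera with the preset correlation called 9 of the 25 lists, 5 higher and 4 lower, and called 0 with an estimated correlation (limma; 3 had an unadjusted p under 0.05, and the smallest adjusted p was 0.395). Fry's directional test called 4, namely DNA replication (adjusted p = 0.00862), interferon (0.0155), ATF4 targets (0.0180), and the KCNQ and KCNE list with KCNQ3 itself (2.37e-04), which camera did not call. Fry's mixed test, for members changed in either direction, also passed for lists that camera did not call. These were neuronal (adjusted p = 4.89e-05), epithelial (6.54e-05), KCNQ and KCNE (1.40e-04), and NF-kB (3.13e-04). KCNQ regulators (0.00151), other voltage-gated potassium channels (0.0336), histones (0.0391) and cation transport (0.0476) passed too. Other lists that camera left uncalled did not pass it. It too does not compare a list with other genes. The lists that camera called higher were those of cholesterol synthesis and uptake, respiratory chain, glycolysis and hypoxia, mitochondrially encoded messenger RNAs, and cytosolic ribosomal proteins. The cholesterol list (28 tested, median log2 0.12, adjusted p = 0.00175, and adjusted p = 0.611 with an estimated correlation) had 0 members past the threshold over all genes and 7 higher when adjusted over the list alone, among them SQLE (0.37), which encodes squalene epoxidase. The nuclear-encoded respiratory chain list (58 tested, median 0.12, adjusted p = 1.01e-07, and adjusted p = 0.694 with an estimated correlation) had 0 members past over all genes and 1, NDUFS6, adjusted over the list alone. The glycolysis and hypoxia list (34 tested, median 0.12, adjusted p = 0.00702, and adjusted p = 0.702 with an estimated correlation) had SLC2A1 past over all genes, and adjusted over the list alone SLC2A1 was higher and VEGFA, a hypoxia-induced growth factor, lower (−0.42). The mitochondrially encoded list (13 tested, median 0.19, adjusted p = 0.00702, and adjusted p = 0.702 with an estimated correlation) and the ribosomal list (78 tested, median 0.05, adjusted p = 0.0158, and adjusted p = 0.805 with an estimated correlation) had 0 members past over all genes and 0 adjusted over the list alone.

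The other lower lists were interferon and nucleic acid sensing, p53 targets and DNA replication. The interferon list (26 tested, median −0.11, adjusted p = 0.00513, and adjusted p = 0.395 with an estimated correlation) had 0 members past over all genes and 0 adjusted over the list alone. Its abundant members ADAR and EIF2AK2 were at 0.961 and 0.945 of control. The p53 list (28 tested, median −0.11, adjusted p = 0.00585, and adjusted p = 0.702 with an estimated correlation) had 0 past over all genes. It shares SESN2 (−0.44) and GDF15 with the ATF4 list, so the 2 lists are not independent. Adjusted over the list alone, 7 members were lower, including PPM1D (−0.28) and PLK2 (−0.47), and BAX was higher (0.21). The DNA replication list (35 tested, median −0.06, adjusted p = 0.00585, and adjusted p = 0.395 with an estimated correlation) had 0 past over all genes, and adjusted over the list alone 10 were lower, such as DTL (−0.23) and CDT1 (−0.31), and TYMS was higher. Several of the 9 calls ended when 1 library was left out: p53 targets without overexpression replicates 3 and 4 (0.0810 and 0.0565), glycolysis without overexpression replicate 3 (0.297), the mitochondrially encoded list without control replicates 2 and 3 and overexpression replicate 4 (0.0706, 0.0518 and 0.0579), and the ribosomal list without control replicate 1 and overexpression replicates 2 and 3 (0.691, 0.636 and 0.0595). With offsets for GC content and length, an alternative added after seeing the data, the mitochondrially encoded and interferon calls ended (0.276 and 0.0664) and the ribosomal list turned lower (0.000653). With offsets fitted on genes outside the ribosomal list, its adjusted p = 0.531 with an estimated correlation. Camera with offsets carried more than 1 correction, so these ended and turned calls may come from overcorrection.

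No ion channel gene on the lists other than KCNQ3 passed the gene test over all genes, which misses many small changes. Among the 5 tested KCNQ and KCNE subunits (camera adjusted p = 0.179), KCNQ3 alone passed over all genes. Adjusted over the list alone, 2 were higher, KCNQ3 itself among them, and 1 lower. Without KCNQ3 the list had a camera adjusted p of 0.893. Of 20 other voltage-gated potassium channel subunits (0.546), 0 passed over all genes and KCNAB3 (0.67) passed adjusted over the list alone; KCNG1 was at 17.9 ± 0.88 CPM against 20.8 ± 2.5. Inward-rectifier, two-pore and calcium-activated potassium channels (22 tested, 0.546), and sodium and calcium channels (21 tested, 0.356) had 0 members past over all genes or adjusted over the list alone. Of 23 KCNQ regulators and partners (0.0835), 0 passed over all genes, and 4 were lower adjusted over the list alone, among them NEDD4 (−0.36), a ubiquitin ligase, and GNAQ (−0.19). The cation and osmolyte transport list (24 tested, 0.893) had none by either adjustment.

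In the neuronal cytoskeleton and synapse list (22 tested, median −0.07, camera adjusted p = 0.0835), SYN1 and SNAP25, a vesicle fusion protein, fell. SNAP25 went from 67 to 23 counts over the groups, a ratio of 2.79 after scaling by library size (95% interval 1.71 to 4.69), and adjusted over the list alone 3 were lower, among them SCG3 (−0.84), and 1 was higher. Immediate early genes (33 tested, 0.0747) had 0 past over all genes and 4 lower adjusted over the list alone, including FOSL1 (−0.49) and NR4A1 (−0.24). The NF-kB list (19 tested, 0.0835) had 0 past over all genes and RELB (−0.41) and LIF (−0.57) lower adjusted over the list alone. Mitosis genes (37 tested, 0.115) had 0 and 2 lower by these adjustments. ER chaperones (26 tested, 0.256), heat shock genes (22 tested, 0.546) and replication-dependent histones (21 tested, 0.947) had 0 by both. Of markers of other cell types, the epithelial list (9 tested, 0.181) had 0 past over all genes and, adjusted over the list alone, MUC1 higher and KRT8, KRT18, EPCAM and TJP1 lower. Fibroblast markers (13 tested, 0.947) and blood cell markers (3 tested, 0.805) had 0 by both. Median, mean and test differed in sign for heat shock genes (0.07, −0.03 and higher), fibroblast markers (0.06, 0.02 and lower, but higher without a scaling factor), blood cell markers (0.04, −0.08 and lower), and cation transport (0.01, 0.01 and lower). Camera called the immediate early list (adjusted p = 0.702 with an estimated correlation) without control replicate 2 (0.0160) and overexpression replicates 1 and 3 (0.0265 and 0.0424), and with all libraries at a mean of 50 counts (0.0407) and with the replicate block (0.0375). It called mitosis without control replicates 1 and 3 and overexpression replicates 3 and 4 (0.0421, 0.0245, 0.0359 and 0.0423), the NF-kB and KCNQ regulator lists without overexpression replicate 3 (0.0479 and 0.0359), and the neuronal list without control replicate 4 (0.0397). For these 4 lists, in that order, the adjusted p = 0.747, 0.582, 0.694 and 0.582 with an estimated correlation and all libraries.

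At the level of single transcripts, 6 of 47129 passed edgeR's quasi-likelihood test, 4 higher and 2 lower, and both KCNQ3 transcripts were among them (adjusted p = 0.0406 and 0.0460). For SUCLA2, which encodes a subunit of succinyl-CoA synthetase, an isoform was higher and another lower, by the authors' division of reads. ENST00000643246 had 10 or 11 counts in controls and 57 to 77 in overexpression libraries, ENST00000646804 had 111 to 165 and 0, and the gene as a whole was not called (adjusted p = 0.887). ENST00000638824 of the kinase gene NEK1 had 0 counts in controls and 240 to 376 in overexpression libraries, with the gene at an adjusted p of 0.423. ENST00000651128, which had no match in the annotation used, had 161 to 204 counts in controls and 12 to 21 in overexpression libraries. The test was imprecise, with 2632 transcripts at an unadjusted p under 0.05 and a biological coefficient of variation of 0.832 against 0.149 for genes. Without a library the count ran from 0 (without control replicate 2 or 4, or overexpression replicate 1, with 2641, 3148 and 3186 at an unadjusted p under 0.05) to 9 (without control replicate 3), and was 1 without overexpression replicate 3. The calls were largely of other transcripts: 0 of 6 without control replicate 1, 3 of 9 without control replicate 3, 1 of 7, 0 of 1 and 1 of 6 without overexpression replicates 2, 3 and 4 were among the 6. With all libraries DESeq2 called 725 transcripts and limma-voom 7.

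For transcript usage, diffSpliceDGE called 33 of 9395 genes, but it also called 97 genes in simulated data without any change, so these calls are given as values only. The 5 with the smallest adjusted p were DCAF8, TMCO1, TMEM126A, YAP1 and ZNF117. In TMEM126A, ENST00000304511 held 70.4% ± 4.5 of the tested counts in controls and 90.6% ± 3.4 in overexpression libraries, while ENST00000528105 went from 18.3% ± 3.5 to 0%. In ZNF117, ENST00000282869 held 92.6% ± 0.74 and 59.8% ± 11.6, and ENST00000620222 0% and 33.4% ± 11.9. In DCAF8, ENST00000368074 held 0% in controls and 25.2% ± 18.2 in overexpression libraries. In TMCO1, ENST00000612311 held 25.8% ± 4.6 and 48.1% ± 18.8. In YAP1, ENST00000615667 held 23.99% ± 15.6 and 31.2% ± 7.2. Of the 33 genes, 27 had a transcript with counts in 1 group alone, and 0 were called at the gene level. The test that keeps each transcript's own spread, added after seeing the data, called 1 gene, SUCLA2 (adjusted p = 0.0451), which was also among the 33. With any 1 library left out diffSpliceDGE called 115 to 155 genes.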

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

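Among 145 groups of 4 libraries examined for the named genes and total counts, 8 (5.52%) had a library standing apart, where chance gives about 5%, or 1 in 20. The measure is the gap to the nearest library divided by the group's range. It was 1 for GH1 in controls, where control replicate 4 had the single count. It was 0.855 for VLDLR-AS1 (control replicate 2 lowest), 0.862 for PIP5K1A (control replicate 3 highest), 0.934 for BUB3 and 0.946 for ATP5F1A (control replicate 1 lowest in both). In the overexpression group it was 0.886 for ASNS (replicate 1 lowest), and 0.872 for RPS6 and 0.889 for ATP5F1A (replicate 2 highest in both).

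GH1 reads appeared with the construct, at 1.31 to 2.87 counts per 100 counts of KCNQ3. The tests of paralogues and of a plasmid source were chosen only after the counts were seen. Sequence shared with KCNQ3 is argued against, since the longest identical stretch between annotated transcripts of the genes was 13 bases, and it was 11 bases for SUGT1P1. Reads spilling over from an expressed paralogue are argued against too: GH2, CSH1, CSH2 and CSHL1 together had 15 counts in the overexpression libraries against 1581 for GH1. A candidate explanation is a growth hormone polyadenylation sequence in the plasmid, which many expression plasmids carry, but the ratio of GH1 to KCNQ3 counts varied 2.19 times between libraries, the plasmid sequence was not used here, and this cannot be told apart from expression of the endogenous gene.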

How the results depend on the processing

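The level of KCNQ3 stayed higher and past the threshold in all 20 alternatives. The gene count of 58 stayed within 1.5 times with DESeq2's size factors, with scaling computed without KCNQ3 and the mitochondrial genes, and with either other filter (56 to 60). It was 35 with no scaling factor, 727 with DESeq2, 29 with limma-voom, 7 on log2(TPM + 1) and 7 on log2(TPM + 0.1), 9 at an adjusted p under 0.01, 4 for a change beyond 1.5 times (KCNQ3, GH1, SUGT1P1 and CELF3), and 8 to 378 with a library left out. With offsets for GC content and length, added after seeing the data, it was 267, which included all 58. The transcript count of 6 was 0 with no filter (4815 at an unadjusted p under 0.05), 725 with DESeq2, 42 and 58 on log2(TPM + 1) and log2(TPM + 0.1), and 0 to 9 with a library left out. Usage calls, 33, were 814 with no filter, 10 for transcripts of at least 10% of their gene, 58 with the gene-level F test, 115 to 155 with a library left out, and 1 with each transcript's own spread (added). Lists called by camera, 9, were 0 with an estimated correlation (3 at an unadjusted p under 0.05), and fry's directional test called 4, 3 of them among the 9. Fewer libraries or a stricter null explain some of these by construction, and otherwise the cause was not tested. Leaving out assembled transcripts gave no value, since the tables hold none.

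The replicate numbers did not pair the libraries: same-numbered libraries correlated at −0.046 to 0.014, 0 of 4 over 0.1, and 0 correlated best with their own number. With the replicate block edgeR called 86 genes, 30 of them among the 58, 0 transcripts (2025 at an unadjusted p under 0.05), 20 usage genes and 10 lists.

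For named genes, 1157 results under alternatives were on the same side of the threshold, 224 lost the call and 25 changed sign. For the 6 named transcripts 57 calls were lost. For lists 20 calls were lost and 12 gained. Every sign change of a gene was between values that did not pass. KCNC4 was 0.19 and 0.22 on the TPM scales and −0.19 to 0.071 with a library left out. CACNA1H was 0.035 with the offsets and −0.071 to 0.018 with a library left out. CANX was −0.100 in both on TPM, and −0.013 to 0.053 with a library left out. With the offsets SOD2 was 0.0073, REL 0.0050 and BUB3 0.014. On TPM (pseudocounts 1 and 0.1), MDM2 was −0.149 and −0.153, BUB3 0.125 and 0.126, FASN −0.0319 and −0.0323, ATP5F1B −0.000195 and −0.000196, and ATP5F1A −0.409 and −0.411. FASN was −0.022 to 0.049 with a library left out. The usage change of ENST00000345877 of YAP1 turned to 0.22 with no filter, 0.16 at a mean of 50 counts, and was −0.30 to 0.50, above 0 in 6 of 8, with a library left out.

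Lists whose direction turned had these camera adjusted p-values. Those with offsets carry more than 1 correction, as described above. With the offsets they were 0.831 for inward-rectifier and related potassium channels, 0.139 for sodium and calcium channels, 0.723 for KCNQ regulators, 0.0664 for cation transport, 0.0621 for histones, 0.353 for fibroblast markers, and 0.000653 for ribosomal proteins, the 1 turned list that was called (with offsets fitted outside that list, adjusted p = 0.531 with an estimated correlation). The KCNQ list was at 0.893 without KCNQ3. With a library left out, cation transport was at 0.445 to 0.894, histones at 0.310 to 0.879, fibroblast markers at 0.567 to 0.894, and blood cell markers at 0.407 to 0.943, and they turned in 3, 3, 4 and 1 of 8. Histones were at 0.961 with the replicate block, fibroblast markers at 0.966 with no scaling factor, and blood cell markers at 0.707 at a mean of 50 counts.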

Other observations

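Genes named in this paragraph were chosen after their values were seen. Among the 58 genes, IARS1, the isoleucyl-tRNA synthetase, fell by 0.24 on the log2 scale and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, by 0.33. RIMS3, a presynaptic protein, fell by 0.43, from 31.7 to 23.5 CPM. Among genes with means below 1 CPM in both groups, COL6A5, a collagen VI chain, went from 0.701 CPM to 0 in all 4 overexpression libraries, CCDC178 from 0.734 to 0.028 CPM, and ZNF750, an epidermal transcription factor, from 0.782 to 0.164 CPM. In the same range NPR3, a natriuretic peptide receptor, went from 0.758 to 0.255 CPM and MYPN, a sarcomeric protein, from 0.954 to 0.306 CPM. SLC5A6, the vitamin transporter, rose by 0.26, and BCAP31, an endoplasmic reticulum protein, by 0.22.

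The 8 libraries can be split into groups of 4 in 35 ways. The labelled split gave 58 genes and the highest of the others 5 (1 of 35 splits as large, the smallest share possible). This argues against chance for the number of genes but cannot exclude it. The other splits mix the labelled groups, so real differences widen the spread within them and can lower their counts. Chance could not be excluded for the other counts either. As many transcripts (6) came from 17 of the 35 splits, with up to 28 in the others. As many usage calls (33) came from 27 splits, with up to 52. As many gene lists (9) came from 7 splits, with up to 11 and a median of 7 in the others.

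Some tests of the patterns that follow were chosen only after the result was seen, namely those that fit offsets on GC content and length. The lower values of ATF4 targets are not accounted for by such a trend: with offsets fitted on genes outside the list, the median was −0.32 (SD of members 0.18) against −0.31 (SD 0.17) without, beyond the spread of the members. Camera called it after the offsets with the preset correlation (adjusted p = 7.12e-16) and, as before them, not with an estimated correlation (adjusted p = 0.537). These camera results carry more than 1 correction, whereas the median carries 1. Of 10000 random lists matched on expression, GC content and length, 0% had a median as low, and the lowest was −0.06. Their genes were drawn independently and lack the shared movement of the ATF4 targets (estimated correlation 0.504). The 0% thus bears on those 3 properties and does not measure chance between libraries. An effect of KCNQ3 and a difference in the state of the cultures, such as density, nutrients or exposure to transfection reagent, both stay open and untested, because the labels do not say how the controls were handled.

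The lists of short genes that camera placed higher were examined with offsets fitted in the same way. The ribosomal list, with a median length of 900 bases against 2430 for all genes, went from a median of 0.05 (SD 0.07) to 0.0049 (SD 0.07). A GC content or length trend is therefore a candidate explanation for its higher values. Camera placed the list lower (adjusted p = 4.98e-04, and adjusted p = 0.531 with an estimated correlation). Camera carried more than 1 correction here, so a fall of the list cannot be read from that call. The respiratory chain list went from 0.12 (SD 0.11) to 0.080 (SD 0.11) and stayed higher by camera with the preset correlation (adjusted p = 0.0160) but not with an estimated correlation (adjusted p = 0.540). The median was reduced by less than its spread and then lay within it. Without offsets the list scores overlapped between groups (exact two-sided permutation p = 0.0857). The trend, a change of these genes and spread between libraries cannot be told apart. The mitochondrially encoded list went from 0.19 (SD 0.08) to 0.136 (SD 0.08), a reduction by less than its spread. Its camera call ended (adjusted p = 0.266, and adjusted p = 0.802 with an estimated correlation). Because camera carried more than 1 correction, the end of the call cannot be laid to the trend. Its scores without offsets also overlapped between groups (exact two-sided permutation p = 0.171). Here too the trend, a change of these RNAs and spread between libraries cannot be told apart.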
